A study of Bos taurus with 10 samples.

How the data were processed

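Epithelial cells of the oviductal isthmus, the segment of the bovine oviduct nearest the uterus, of heifers (Bos taurus) were profiled by RNA sequencing in 10 libraries, 5 from cyclic animals given a sham transfer and 5 from pregnant animals, each of which had received 50 presumptive zygotes made in vitro. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was selected with oligo-dT beads, and stranded TruSeq libraries were amplified by PCR and sequenced on a HiSeq 2500. The aligner, the read counter, the genome build and the annotation release are not given in the sources used here. Groups were taken from the treatment given in the labels. The labels do not state that each library is from a separate animal, so p-values measure the spread between these libraries, and n counts libraries throughout.

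The authors deposited 1 table of 24596 features by 10 libraries, whose header calls the values only expression. The deposited values behaved as RPKM (reads relative to gene length and library total): within a gene the low values were whole multiples of a step that depended on the gene, with a fixed ratio between libraries. The table therefore holds normalised values, and no test made for counts was used as the main test. The analysis fixed before the data were examined had named a count test first and, for a table of normalised values, the limma test used here. Features carry the names in the table, which are symbols, Ensembl identifiers, or symbols with a copy number at the end. Of the 12834 tested features, 11289 matched a name in the reference gene table, and 222 carried a copy number. Reads of such copies could have been divided between near-identical loci, so their values are uncertain.

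Because RPKM is a read number divided by a library total and a gene length, both were recovered from the table. A search for the totals and whole-base lengths at which all 10 values of a feature become whole reads resolved 12791 of the 12834 tested features, with a tolerance of 0.02 reads plus the rounding of the deposited values. Of 500 features with jittered values, 0.2% were resolved at the accepted lengths of up to 12000 bases. For 13 of 13 mitochondrial genes the recovered length equalled the annotated length. On simulated tables, 100% of 1500 features had all of their reads recovered. The recovered totals ran from 9.71 M reads (M, mega) in cyclic library 4 to 26.1 M in pregnant library 5. A gene of 1 kilobase gains 0.103 RPKM per read in the first and 0.0383 in the second, so values near or below these rest on single reads.

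The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1) for features with a mean RPKM of at least 1, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are pregnant minus cyclic on that log2 scale, which understates the change of low genes, and errors are limma's standard errors (SE). On simulated values for the 12834 genes of this comparison with independent residuals, 78 of 100 genes changed by 1 log2 unit and 99 of 100 changed by 2 units were called, with 9 false calls. With residuals that kept the correlation between genes, 77 and 99 were called, with 1 false call. Each result rests on 1 draw with 200 genes changed, so neither gives a rate of false calls or the recovery to expect in the data.

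Gene lists for cell types and responses, 26 in all, were fixed before the data were examined. Lists with at least 5 tested members (22) were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. List members absent under their current symbol were matched through the table's descriptions or the synonyms in the reference gene table. Genes were named by a rule fixed at the same time. It takes up to 12 genes per direction of smallest p among those passing, or, where fewer than 5 pass, the 5 of smallest p. It adds up to 4 tested members of each list, and always OVGP1, PAX8, FOXJ1, PGR, ESR1, ISG15, MX1, MX2, PTPRC, EPCAM, ZP3 and GDF9. A gene taken by this rule is not reported here. Library totals were compared with a two-sided exact permutation test over 252 assignments.

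Other settings listed before the data were examined were a pseudocount of 0.1, no filter on low values, sample array weights in place of the trend, a threshold of 0.1, each library left out in turn, and the library number as a block. Settings added after seeing the data were other scalings, a stricter filter, a robust prior, voom on the recovered reads with and without quality weights, and leaving out cyclic libraries 1 and 4 together. Settings listed beforehand that need deposited counts were not run. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene sequence was not used here, so GC content was not examined.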

Results

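RPKM values were available for isthmic oviduct epithelial cells of cyclic heifers (5 libraries) and pregnant heifers (5 libraries). The comparison asked whether the presence of embryos in the oviduct altered the transcriptome of the cells lining it. Recovered library totals were 16.4 ± 3.79 M reads in cyclic and 19.8 ± 4.02 M in pregnant heifers (SD, n = 5 each). These totals did not differ by more than the spread between libraries (difference 3.48 M, two-sided exact permutation p = 0.254).

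OVGP1, which encodes the oviduct-specific glycoprotein secreted around gametes and embryos, averaged 5760 ± 2170 RPKM in cyclic and 2050 ± 1160 RPKM in pregnant heifers (SD, n = 5 each). CLU, the secreted chaperone clusterin, averaged 1650 ± 694 RPKM against 500 ± 108 RPKM, and MUC1, a membrane mucin, 62.9 ± 24.3 RPKM against 19.1 ± 13.6 RPKM. Neither these genes nor any other of the 12834 genes tested passed an adjusted p of 0.05 (limma-trend, smallest adjusted p = 0.0934), although 3534 genes (27.5%) had an unadjusted p under 0.05, of which 2009 were higher and 1525 lower in pregnant heifers. As lists, genes of the secretory epithelium, immediate early genes and complement and antimicrobial genes were lower in pregnant heifers, and genes of cholesterol biosynthesis were higher (camera, adjusted p = 0.000228, 0.000187, 0.0442 and 0.00188). None of these 4 calls held with an estimated correlation, where adjusted p was 0.668, 0.601, 0.668 and 0.844.

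Of the genes with the smallest p, none of which passed, the 5 lower in pregnant heifers were KCNE3, PRKCSH_2, C2ORF17, RARA and KDELR1. KCNE3, a regulatory subunit of potassium channels, averaged 46.6 ± 19.8 RPKM in cyclic and 13.2 ± 2.28 RPKM in pregnant heifers (SD, n = 5 each), a log2 difference of -1.66 (SE 0.25). RARA, a retinoic acid receptor, averaged 23.1 ± 3.29 against 13.4 ± 1.02 RPKM, with a log2 difference of -0.73. KDELR1, which returns proteins to the endoplasmic reticulum, averaged 53.3 ± 5.46 against 32.2 ± 4.04 RPKM. C2ORF17, described in the table as FAM134A, had a log2 difference of -0.89. PRKCSH_2 differed by -1.02, and as a numbered copy its value is uncertain. The 5 higher in pregnant heifers were DDHD1, ENSBTAG00000033759, ARAP2, MPP7 and LTV1. DDHD1, a phospholipase, averaged 8.95 ± 2.07 RPKM in cyclic and 19.4 ± 3.82 RPKM in pregnant heifers, a log2 difference of 1.04 (SE 0.17). MPP7, a scaffold protein of cell junctions, averaged 32.3 ± 6.62 against 66.9 ± 14.8 RPKM, and LTV1, a factor in assembly of the small ribosomal subunit, 10.1 ± 1.28 against 16.8 ± 1.97 RPKM. ARAP2 differed by 0.79 and the uncharacterised locus ENSBTAG00000033759 by 1.53. All 10 of these genes had an adjusted p of 0.0934 (limma-trend), a value shared by 438 tested genes, and no overlap between the libraries of the groups. Over all tested genes, 893 (6.96%) showed no overlap, where chance gives 0.79%.

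**Figure D1:**
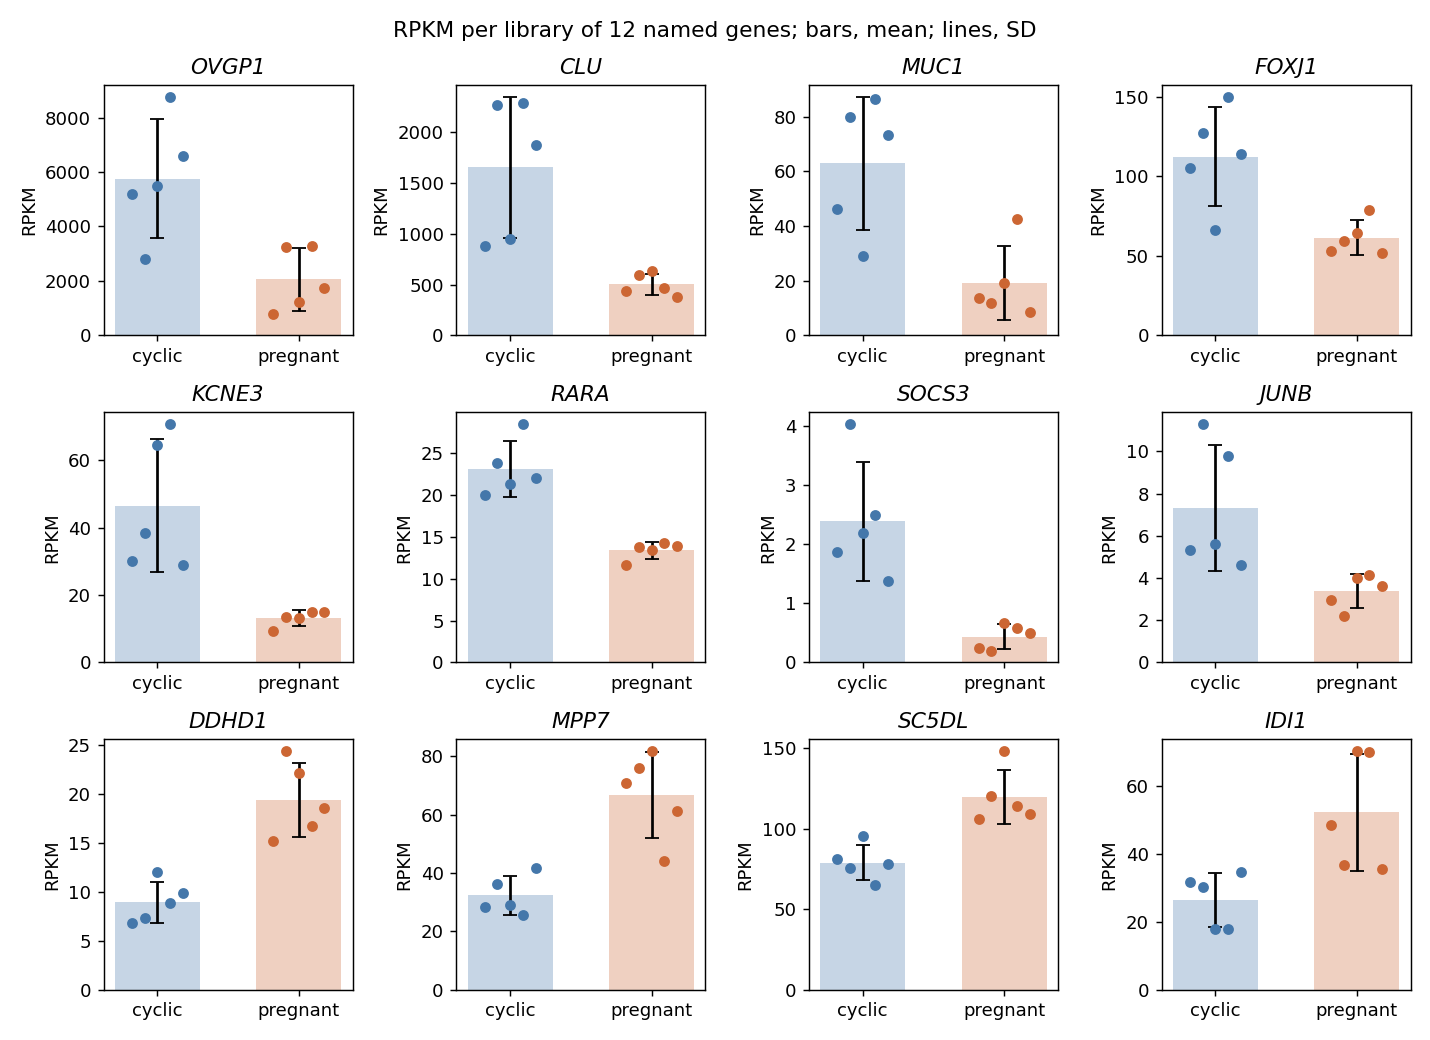
RPKM of 12 named genes in each library, with bars for the mean of 5 cyclic and 5 pregnant libraries and lines for the SD; each vertical axis starts at 0. OVGP1 averages 5760 RPKM in cyclic and 2050 RPKM in pregnant heifers with overlapping libraries, whereas the libraries of KCNE3, RARA and DDHD1 do not overlap.

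Of 19 tested secretory epithelium genes, 16 were lower in pregnant heifers, with a median log2 difference of -0.52. None passed over all genes, and 4 were lower when adjusted over the list alone. Log2 differences were -1.78 for MUC1, -1.63 for CLU, -1.61 for OVGP1 (95% interval -2.56 to -0.66) and -0.73 for KRT8, a keratin of simple epithelia. PAX8, a transcription factor of secretory cells, averaged 87.5 ± 14.9 RPKM in cyclic and 88.1 ± 5.99 RPKM in pregnant heifers (SD, n = 5 each; log2 difference 0.02, interval -0.25 to 0.3). EPCAM, an adhesion molecule of epithelia, averaged 365 ± 39.1 against 330 ± 15.4 RPKM (log2 difference -0.14).

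Among 22 tested genes of ciliated cells, 15 were lower and 7 higher, with a median of -0.11 and no call (camera adjusted p = 0.105). None passed over all genes; 6 were lower and 2 higher when adjusted over the list alone. FOXJ1, the transcription factor that drives formation of motile cilia, averaged 113 ± 31.1 RPKM in cyclic and 61.4 ± 11.1 RPKM in pregnant heifers (log2 difference -0.83). The axonemal dynein genes DNAI1, DNAI2 and DNAH9 had log2 differences of -0.53, -0.61 and -0.43. CCDC39, which sets the spacing of dynein arms, and ENKUR lay in the other direction, at 0.96 and 0.85.

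Of 19 tested immediate early genes, 17 were lower in pregnant heifers (median log2 difference -0.53), and 8 were lower when adjusted over the list alone, none over all genes. The list averaged -0.077 in cyclic library 3, level with pregnant libraries 3 and 4 (-0.103 and -0.072), and 0.158 to 0.573 in the other cyclic libraries (log2, centred on all libraries). SOCS3, an inhibitor of cytokine signalling, averaged 2.39 ± 1.01 RPKM in cyclic and 0.439 ± 0.208 RPKM in pregnant heifers (SD, n = 5 each; log2 difference -1.2). MYC, JUNB and IER3 had log2 differences of -1, -0.87 and -0.71. In cholesterol biosynthesis, 20 of 23 tested genes were higher in pregnant heifers (median 0.54), 4 of them when adjusted over the list alone and none over all genes. The list averaged -0.771 in cyclic library 3 and 0.629 and 0.617 in pregnant libraries 3 and 4 (log2, centred on all libraries), while pregnant libraries 2 and 5 (-0.163 and -0.248) lay within or below the -0.174 to 0.197 of the other cyclic libraries. Without cyclic library 3 the list's median was 0.34. SC5DL, a sterol desaturase, averaged 78.9 ± 10.9 against 119 ± 17.2 RPKM, and CYP51A1, a sterol demethylase, 29.4 ± 8.51 against 53.6 ± 13.8 RPKM. IDI1 and HMGCS1, enzymes of the mevalonate pathway, differed by 0.95 and 1.06. Of 20 tested complement and antimicrobial genes, 15 were lower (median -0.39), none of them significant over all genes or when adjusted over the list alone. The list averaged 0.471 in pregnant library 5, above every cyclic library except cyclic library 2 (0.592), and -0.099 in cyclic library 5, among the pregnant values. The difference in its mean ran from -0.59 without pregnant library 5 to -0.28 without pregnant library 1. SERPING1, an inhibitor of the first complement component, averaged 9.03 ± 5.01 against 3.26 ± 1.3 RPKM. ENSBTAG00000037533, matched to C4A, PIGR and C3 differed by -0.84, -0.78 and -1.69, and C3 belongs to the secretory list as well. PIGR differed by -0.5 without cyclic library 2 and by -1.31 with array weights, which weigh that library most among the cyclic ones (2.78). C3 differed by -1.09 without pregnant library 1.

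**Figure D2:**
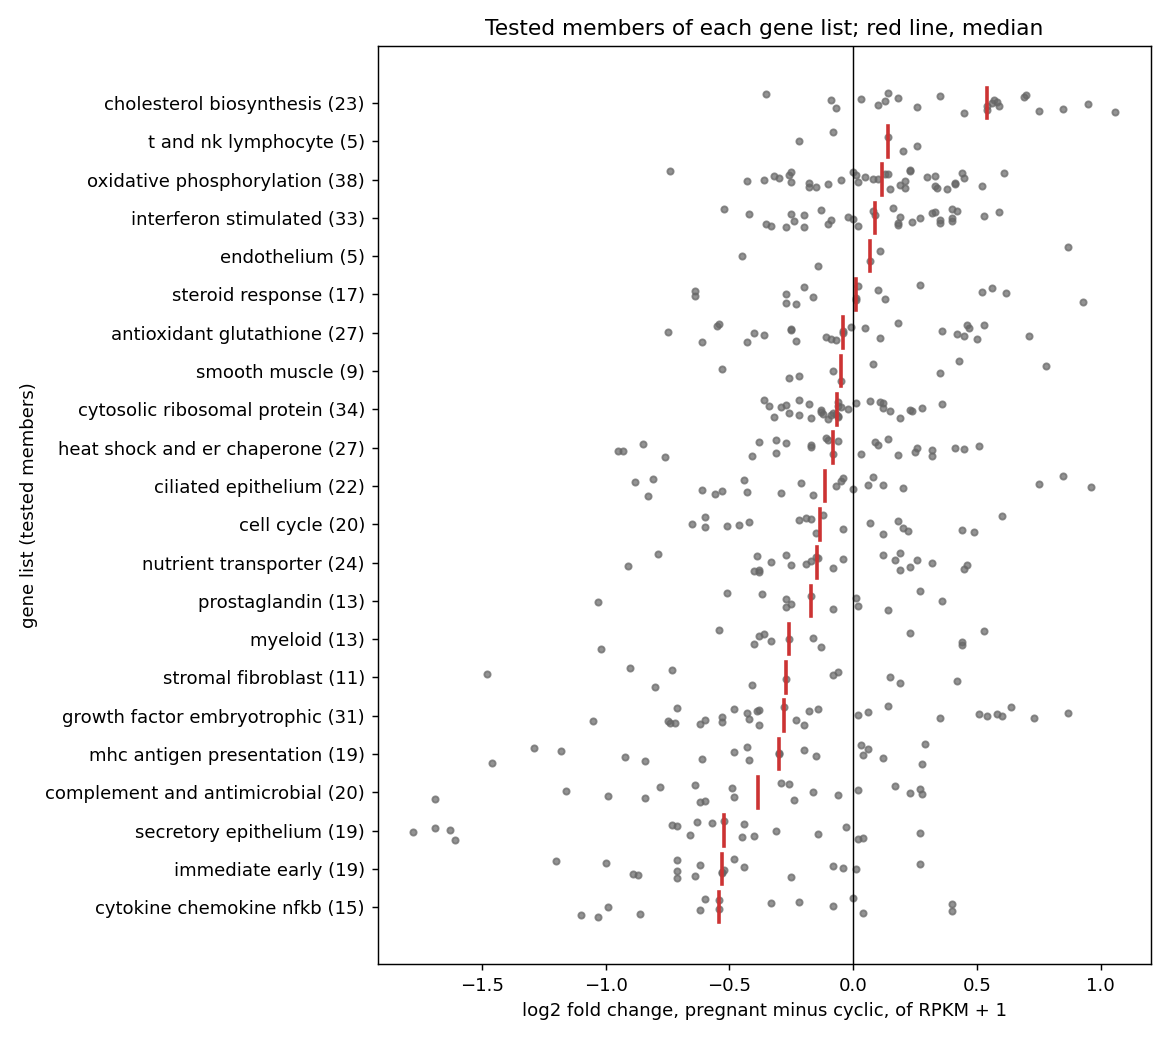
Log2 fold change (pregnant minus cyclic, of RPKM + 1) of each tested member of the 22 lists with at least 5 tested members, a grey point per gene and a red line at the list's median. The secretory and immediate early lists have medians of -0.52 and -0.53, and cholesterol biosynthesis has a median of 0.54.

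Markers of other cells in the sample were mostly low. The 17 stromal fibroblast genes summed to 113 ± 23.6 RPKM in cyclic and 64.4 ± 13.9 RPKM in pregnant heifers (SD, n = 5 each), beside 9380 ± 2620 and 4040 ± 985 RPKM for the secretory list. The stromal list was not called (11 tested, median -0.27, adjusted p = 0.203), with FBLN1 at -1.48, FN1 at -0.9, COL1A2 at -0.8 and SPARC at -0.73. SPARC differed by -0.41 without cyclic library 4 and by -0.2 with array weights. The FN1 difference was smaller with array weights as well. The difference in the list's mean went from -0.36 to -0.22 without cyclic library 1. When adjusted over the list alone, 1 stromal gene was lower. Smooth muscle genes had a median of -0.05 (camera adjusted p = 0.845), and 1 gene was lower when adjusted over the list alone. SYNM differed by -0.53, MYLK by 0.78, TPM2 by 0.43 (0.15 without pregnant library 4) and CNN1 by 0.35. CNN1 stood at 3.31 RPKM in pregnant library 4 and at 0.761 to 1.14 RPKM in the other pregnant libraries. Its difference was smaller without that library. Endothelial genes had a median of 0.07 (adjusted p = 0.845), with EMCN at 0.87, KDR at -0.45 (-0.15 without cyclic library 4), TEK at 0.11 and ENSBTAG00000012066, matched to PECAM1, at -0.14. T and NK lymphocyte genes had a median of 0.14 (adjusted p = 0.82), with CD2 at 0.26, LCK at -0.22, CD3E at 0.2 and CCL5 at 0.14. Myeloid genes had a median of -0.26 (camera adjusted p = 0.336), with AIF1 at 0.44, FCER1G at -0.36, CD14 at -1.02 and TYROBP at -0.38. TYROBP stood at 4.08 RPKM in cyclic library 4 and at 1.1 to 3.02 RPKM in the other cyclic libraries. Its difference was smaller without that library. The difference in the mean of the myeloid list, -0.15, went to -0.02 without cyclic library 2 and to -0.31 without cyclic library 1. PTPRC, expressed by all leukocytes, averaged 2.22 ± 0.547 against 2.99 ± 0.756 RPKM. The B lymphocyte, erythrocyte, cumulus and oocyte lists had under 5 tested members and were not tested as lists. MZB1 and IGJ of plasma cells differed by 0.6 and 0.74, and the erythroid gene AHSP by -0.03. Of the cumulus and granulosa genes, STAR and INHA differed by -0.15 and -0.12. When adjusted over the list alone, 1 of the 2 tested B lymphocyte and plasma cell genes was higher.

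Transcripts of the transferred embryos were looked for with oocyte and early embryo genes. OOEP averaged 9.17 ± 0.951 RPKM in cyclic and 7.25 ± 2.44 RPKM in pregnant heifers (SD, n = 5 each), BTG4 1.65 ± 0.719 against 2.33 ± 0.923 RPKM, and NOBOX 0.934 ± 0.389 against 1.08 ± 0.128 RPKM. GDF9, an oocyte growth factor, averaged 0.656 ± 0.172 against 0.612 ± 0.16 RPKM, and ZP3, a protein of the zona pellucida, 0.033 ± 0.0335 against 0.0248 ± 0.023 RPKM. ZP3 reached at most 0.079 RPKM, where 1 read in a gene of 1 kilobase is worth 0.0383 to 0.103 RPKM. None of OOEP, BTG4 and NOBOX differed by more than the spread between libraries (limma-trend, smallest adjusted p = 0.235). No embryo contribution was therefore detectable with these genes at this depth. They were also present in cyclic heifers, so a small contribution could not be seen with them. Below the filter, POU5F1 was 0 RPKM in all libraries and NANOG reached at most 0.036 RPKM. These low values do not show that the transcripts were absent, since 6025 features were 0 in all libraries. The antioxidant gene GPX4 was among them. COX6B1 of oxidative phosphorylation reached at most 0.362 RPKM, while COX6C averaged 144 RPKM in cyclic heifers. NLRP5 reached 1.19 RPKM, with means of 0.802 in cyclic and 0.692 in pregnant heifers.

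Interferon-stimulated genes, which respond to interferon tau from the ruminant conceptus later in pregnancy, showed no call (33 tested, median 0.09, adjusted p = 0.436). ISG15 averaged 7.02 ± 2.43 RPKM in cyclic and 9.43 ± 11.8 RPKM in pregnant heifers (SD, n = 5 each), with 29.7 RPKM in pregnant library 4 and 0.383 to 8.94 RPKM in the other pregnant libraries. Its log2 difference was -0.27 (interval -1.67 to 1.13), opposite in sign to the difference in means. MX1 averaged 37.5 ± 7.98 against 36.6 ± 19.5 RPKM and MX2 10.4 ± 1.77 against 10.7 ± 2.79 RPKM. IFIT5, HERC5 and IFIH1 differed by 0.35, 0.4 and 0.53, and ZNFX1 by -0.52. Genes of antigen presentation had a median of -0.3 (adjusted p = 0.0828), with TAPBP at -1.18, JSP.1 at -1.46, CD74 at -1.29 and BOLA-NC at -0.84. Reads of class I genes such as JSP.1 could have been divided between near-identical copies, so their values are uncertain. Cytokine, chemokine and NF-kappaB genes had a median of -0.54 (adjusted p = 0.0886), with CXCL16 at -0.62, ICAM1 at -0.6, TNFAIP3 at -0.54 and IL18 at 0.4. This list averaged 1.123 in cyclic library 2 and -0.367, -0.068 and -0.123 in cyclic libraries 1, 3 and 4 (log2, centred on all libraries), within the -0.603 to 0.195 of the pregnant libraries. Without cyclic library 2 the difference in its mean went from -0.4 to -0.17, and ICAM1 and TNFAIP3 differed by -0.35 and -0.33. With array weights, the largest of which among cyclic libraries was that of cyclic library 2 (2.78), those 2 genes differed by -0.92 and -0.74.

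The steroid receptors PGR and ESR1 averaged 32.1 ± 12.5 and 200 ± 84.9 RPKM in cyclic and 26 ± 4.1 and 158 ± 35.3 RPKM in pregnant heifers (SD, n = 5 each; log2 differences -0.23 and -0.27). Cyclic library 1 held the highest value of each receptor (50.8 and 309 RPKM), and both differences turned positive with array weights. The steroid response list had a median of 0.01 (camera adjusted p = 0.965), with FKBP4 and GREB1 at -0.64, HSD11B1 at 0.56 and ESR2 at 0.93. Prostaglandin genes had a median of -0.17 (camera adjusted p = 0.443), with PTGER4 at -0.37, PLA2G4A at 0.27, ABCC4 at -0.51 and ENSBTAG00000023384, matched to CBR1, at -0.27. The ABCC4 difference turned positive with array weights. Growth factor and embryotrophic genes had a median of -0.28 (adjusted p = 0.105), with IGFBP7 at -0.6, IGFBP5 at -1.05, CYR61 at -0.71 and IGF2R at -0.62. Nutrient transporters had a median of -0.15 (adjusted p = 0.407), with AQP5 at -0.79, SLC1A4 at -0.91, SLC2A12 at 0.45 and SLC7A1 at -0.33. Antioxidant genes had a median of -0.04 (adjusted p = 0.763), with GCLM at 0.5, TXN at 0.47, GSTM3 at 0.71 and HMOX1 at -0.55. Chaperones had a median of -0.08 (adjusted p = 0.507), with HSPA1A at -0.76, HSPB8 at -0.93, ERP70 at -0.85 and DNAJB9 at 0.51. Cell cycle genes had a median of -0.14 (camera adjusted p = 0.436), with NUSAP1 at 0.6, MCM7 at -0.42, MCM4 at -0.46 and MCM2 at -0.6. The difference in the mean of the cell cycle list, -0.09, went to -0.02 without cyclic library 5 and to -0.17 without pregnant library 4. Ribosomal protein genes had a median of -0.07 (adjusted p = 0.336), with RPLP0 at -0.36, RPL13 at -0.34 and RPL8 at -0.29. Nuclear genes of oxidative phosphorylation had a median of 0.11 (adjusted p = 0.203), with ATP5D at -0.74, COX7A2 at 0.61, NDUFS1 at 0.41 and COX6C at 0.44. Of that list, 1 gene was lower when adjusted over the list alone.

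Libraries of the same group stood far apart. On the first principal component (38.1% of the variance) pregnant libraries 1, 2, 3 and 5 lay between 21.6 and 29.3, and pregnant library 4 lay at -6.5. Cyclic libraries 1, 2, 4 and 5 lay between -55.7 and -10.6, and cyclic library 3 lay at 10.5. The secretory list averaged -0.257 in cyclic library 3 and between -0.066 and 0.708 in the other cyclic libraries (log2, centred on all libraries), and -0.062 in pregnant library 4 against -0.526 to -0.178 in the other pregnant libraries.

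**Figure D3:**
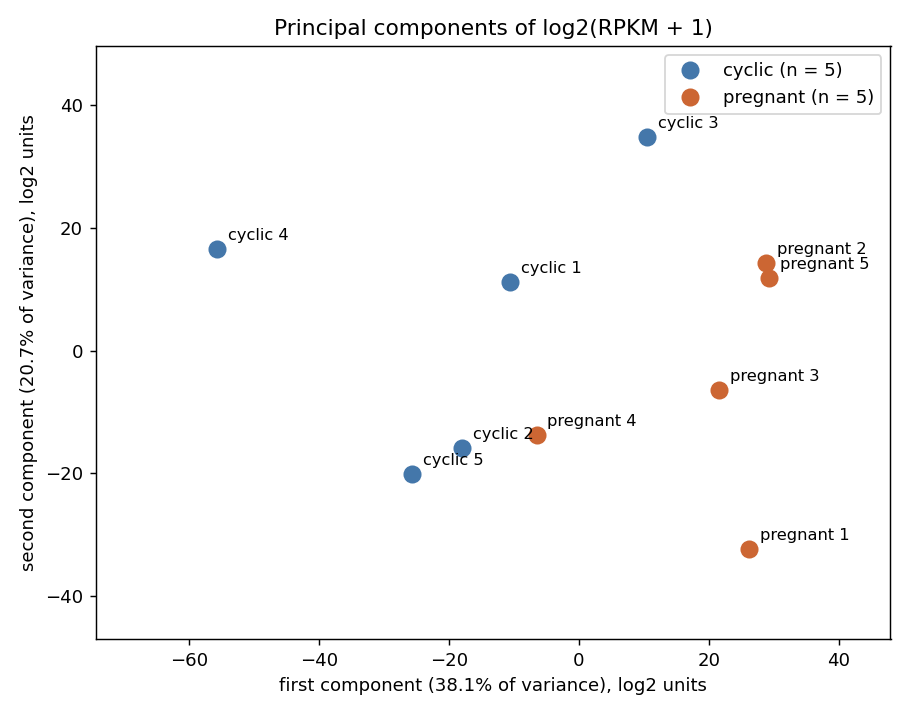
First and second principal components of log2(RPKM + 1) over the 12834 tested genes, a point per library, blue for cyclic (n = 5) and orange for pregnant (n = 5). Cyclic library 3 lies at 10.5 and pregnant library 4 at -6.5 on the first component, which explains 38.1% of the variance.

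The count of 0 genes moved with the weight given to single libraries. It became 2213 without cyclic library 3 and 56 without pregnant library 4. Sample array weights (limma) gave 4789, but they took the place of the trend, so both changed together. On the recovered reads, voom gave 4923 with quality weights and 0 without weights. The complement call was also lost without cyclic libraries 2 or 3 or pregnant libraries 1 or 4 (adjusted p = 0.129, 0.149, 0.161 and 0.171), with median-ratio scaling (0.0736) and with a stricter filter on low values (0.0811), and the cholesterol call without cyclic library 3 or pregnant library 4 (0.137 and 0.0515).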

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

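Tests of gene length, of secretory cell share, of an exchange of 2 libraries and of the adjusted count over other splits were chosen after the results were seen, and principal components and fits without single libraries had been seen before the remaining tests were run. Within a group, a library was singled out where its gap to the nearest other library took up most of the group's range. Among 278 groups of values examined this happened 22 times, with 9 in pregnant library 4 and 6 in cyclic library 4. Chance gives about 13.9 for normally distributed values. Genes were examined as RPKM and not on the log2 scale, so chance could give more, and no excess was shown.

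In pregnant library 4, the smooth muscle genes TPM2 and CNN1 reached 7.32 and 3.31 RPKM, against at most 2.3 and 1.14 in the other pregnant libraries. TAPBP (26.2 RPKM), FKBP4 (80.8 RPKM), PLA2G4A (21.5 RPKM), MYC (5.66 RPKM), MCM2 (2.14 RPKM) and ATP5D (41.1 RPKM) were likewise high there, and ARAP2 (10.4 RPKM) was low. Cyclic library 4 held the fewest reads of its group (9.71 M) and stood high for C2ORF17 (62.4 RPKM), KDELR1 (62.8 RPKM), SPARC (79.6 RPKM), IGFBP5 (15.8 RPKM) and CYR61 (7.14 RPKM). MZB1 (4.21 RPKM) and EPCAM (357 RPKM) stood high in pregnant library 1, and IFIT5 (14.9 RPKM) low in pregnant library 2. JSP.1 reached 566 RPKM in cyclic library 5, whose cell cycle list averaged 0.31 log2 units above the mean of all libraries, against -0.04 to -0.01 in the other cyclic libraries and 0.285 in pregnant library 4. TNFAIP3 reached 3.58 RPKM in cyclic library 2 and HSD11B1 11.2 RPKM in cyclic library 1.

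Many genes had a small unadjusted p and none passed adjustment; the adjusted count of 0 is the lowest possible, so that all 100 splits drawn from the 126 possible had to give as many (highest other 3373) and nothing follows from them. At an unadjusted p under 0.05, 2 of the 100 splits drawn, 1 of them the real grouping, gave 3534 or more genes (highest other 5350). So large a count was rare among the splits drawn, which argues against chance for that count but does not exclude it. Splits that were not drawn could reach it too. The tables argue against gene length (Spearman rho of length and fold change across genes -0.018). Small p were not confined to genes with few reads, since 32.9% of the third of genes with most reads had an unadjusted p under 0.05. That share cannot settle other effects of the difference in depth. The log2(RPKM + 1) scale understates the change of low genes, and this was not separated from depth. GC content was not examined, so an effect of it stays open. An axis on which animals of one group also vary cannot be told apart from the group difference, because the absolute Pearson r across genes between the group difference and the first component within groups was 0.43, between the bounds set, and an effect of pregnancy remains open.

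The calls that appear without cyclic library 3 or with array weights form another pattern. With array weights, 6 of the 100 splits drawn, the real one included, gave 4789 or more genes (highest other 5606), so chance cannot be excluded for that count. The split with the highest counts exchanged cyclic library 3 and pregnant library 4 and called 3373 genes without weights, which points to a structure of the samples, but these 2 libraries had already been seen to lie nearest the other group, so the count adds no independent support. Cyclic library 3 lay nearer to the pregnant mean at 78.7% of the genes called without it, which restates the pattern because those are the genes whose call it removes, and pregnant library 4 lay nearer to the cyclic mean at 60.1% of genes, between the bounds set, so that a wrong label and an exchange both stay open. Animals that differed in cycle stage or in their response to embryos could give the same values, and this was not tested, so the labels were kept.

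OVGP1, CLU and MUC1 were lower in pregnant libraries, which may reflect a lower share of secretory cells or lower expression within them. A lower share as the whole cause needs the other members to be lower by about as much. The mean log2 difference between groups of the 16 others, however, lay 1.24 above that of these 3 genes. The log2 difference of PAX8, named before the data were examined, lay 1.7 above that of the 3 genes. Exact permutation p was 0.00794 for each gap, the smallest the permutations can give (adjusted p = 0.0159). CLU and MUC1 were picked for their low values in pregnant libraries, which widens these gaps. OVGP1 was also named beforehand. Against its log2 difference alone, that of the others lay 1.18 above (exact permutation p = 0.0635, adjusted p = 0.0635). That of PAX8 lay 1.63 above (exact permutation p = 0.0238, adjusted p = 0.0272). These values argue against the share as the whole cause only as far as PAX8 and the other members mark secretory cells in this tissue. EPCAM and KRT8 among them are genes of epithelia, so their values need not follow the secretory share. Against OVGP1 alone, the reference set first, the other members left the question undecided. A part from the share stays open, since 27.8% of the 18 members other than OVGP1 lay above OVGP1 in log2 difference at an exact permutation p under 0.05 (adjusted p = 0.143 for each), between the bounds set, and lower expression per cell was not tested.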

How the results depend on the processing

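The scalings, the stricter filter, the robust prior, both voom fits and the fit leaving out cyclic libraries 1 and 4 were chosen after seeing the data. Counts of 0 genes were also found with a pseudocount of 0.1, no filter, other scalings, a stricter filter, a robust prior and voom on recovered reads. Genes called numbered 4789 with array weights (6180 at an unadjusted p under 0.05), 4923 with voom and quality weights (6295), and 1018 at an adjusted p of 0.1. Leaving out 1 library at a time gave 0 to 2213 genes called and 2567 to 4802 at an unadjusted p under 0.05. Both counts of calls above 0 were without cyclic library 3 (2213) and pregnant library 4 (56). Without cyclic libraries 1 and 4 the unadjusted count was 2113. Of the 4 called lists, 0 were called with an estimated correlation and 0 with fry; 8 lists were called without cyclic libraries 1 and 4, and 2 to 8 with 1 library left out (8 without cyclic library 1 and 8 without pregnant library 2). The secretory and immediate early lists were called with each of the 10 libraries left out, always at the preset correlation of 0.01. Their estimated correlations were 0.28 and 0.17. The replicate block, with the library number as a term, gave 0 genes (smallest adjusted p = 0.062); deviations of libraries with the same number correlated at -0.03, -0.27, -0.01, 0.28 and -0.34, so the numbers were not read as pairs. The difference in library totals ran from 1.81 to 4.19 M with 1 library left out. The count tests listed beforehand were not run because the table holds RPKM. Of 114 tested named genes, 104 kept their direction under every alternative run for them, as did 16 of 22 lists. Most named genes were picked for a small p in the main fit of the same libraries, so a kept direction is no independent support. The cause of the changes was not tested. With array weights the log2 differences became 0.16 for KDR, 0.18 for ENSBTAG00000012066, 0.06 for ABCC4, 0 for PAX8, 0.07 for PGR, 0.12 for ESR1 and -0.12 for MX2. With voom and quality weights they were 0.27 for KDR, 0.28 for ENSBTAG00000012066, 0.11 for ABCC4, -0.01 for PAX8, 0.06 for PGR, 0.14 for ESR1 and -0.13 for MX2. Without cyclic libraries 1 and 4 they were 0.02 for KDR, 0.07 for ENSBTAG00000012066, 0.02 for PGR, 0.15 for ESR1, -0.12 for MX2, and, as medians, 0.11 for the smooth muscle list and -0.01 for the interferon list. Upper-quartile scaling gave -0.06 for PAX8 and -0.05 for MX2, a pseudocount of 0.1 gave 0.02 for AHSP, and median-ratio scaling gave 0 for the steroid response list. With 1 library left out, ranges that reached or crossed 0 were -0.2 to 0.11 for AHSP, -0.04 to 0.1 for PAX8, -0.84 to 0.28 for ISG15, -0.44 to 0.14 for MX1 and -0.08 to 0.13 for MX2. For list medians they were -0.51 to 0.02 (stromal), -0.27 to 0.09 (smooth muscle), 0 to 0.16 (endothelial), -0.02 to 0.23 (interferon), -0.08 to 0.12 (steroid response) and -0.19 to 0.07 (ribosomal protein). Of the third of genes with fewest reads, 19.9% had an unadjusted p under 0.05, against 32.9% of the third with most; depth was not separated here from the log2(RPKM + 1) scale.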

Other observations

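The following gene groups were put together after seeing which genes had the smallest p, so their tests are not independent evidence, and none of their members passed over all genes. Of 41 tested genes of lysosomal hydrolases and other lysosomal proteins, 12 were lower in pregnant heifers when adjusted over the list alone (median log2 difference -0.37). Camera gave an adjusted p of 4.6e-08 over the 6 added lists, and an adjusted p of 0.175 with an estimated correlation. CTSF, a lysosomal cysteine protease, averaged 24.1 ± 4.77 RPKM in cyclic and 12.4 ± 1.66 RPKM in pregnant heifers (SD, n = 5 each), and PSAP, the precursor of the saposins, 168 ± 56.2 against 75.2 ± 22.4 RPKM. Of 9 tested keratin genes, 4 of them shared with the secretory list, 4 were lower when adjusted over the list alone (adjusted p = 0.0057, and adjusted p = 0.175 with an estimated correlation). The keratin list averaged 0.69 in cyclic library 4 and 0.058 to 0.253 in the other cyclic libraries (log2, centred on all libraries). Without cyclic library 4 the difference in its mean went from -0.5 to -0.39. KRT5, a keratin of basal cells, averaged 39.2 ± 25.8 against 11.8 ± 3.41 RPKM. Genes of cargo transport between endoplasmic reticulum and Golgi had a median of -0.24 (34 tested, adjusted p = 0.00212, and adjusted p = 0.343 with an estimated correlation), with NUCB1 at -0.96 and LMAN1 at 0.5, and 4 were lower and 2 higher when adjusted over the list alone.

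Of the 13 genes encoded in mitochondria, 5 were higher in pregnant heifers when adjusted over the list alone (median 0.34, camera adjusted p = 0.000922, and adjusted p = 0.243 with an estimated correlation). ATP8 averaged 1850 ± 347 RPKM in cyclic and 3320 ± 372 RPKM in pregnant heifers (SD, n = 5 each), and ND2 660 ± 173 against 1210 ± 112 RPKM. Of 15 tested golgin genes, which encode long coiled-coil proteins of the Golgi, 8 were higher and 2 lower when adjusted over the list alone (adjusted p = 0.018, and adjusted p = 0.175 with an estimated correlation). The golgin list averaged -0.54 in cyclic library 4 and -0.139 to -0.071 in the other cyclic libraries (log2, centred on all libraries). Without cyclic library 4 the difference in its mean went from 0.39 to 0.3. GOLGA4 averaged 11.7 ± 4.41 against 25.8 ± 4.98 RPKM and GCC2 10 ± 3.63 against 20.7 ± 4.98 RPKM. Of 31 tested centriole and coiled-coil ciliary genes, 14 were higher and 1 lower when adjusted over the list alone (adjusted p = 6.68e-05, and adjusted p = 0.284 with an estimated correlation). This list averaged -0.922 in cyclic library 4, which had the fewest reads, against -0.246 to 0.095 in the other cyclic libraries and -0.006 to 0.334 in the pregnant libraries (log2, centred on all libraries). Without cyclic library 4 the difference in its mean went from 0.48 to 0.31. MAP9 averaged 7.2 ± 2.21 against 15 ± 3.06 RPKM, and ENKUR, also a member of the ciliated list, 43.8 ± 15.6 against 75.4 ± 10.6 RPKM.

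Both features named next were chosen after their values were seen. ENSBTAG00000047264, described in the table as an uncharacterised protein, stood at 26100 RPKM in cyclic library 1 and between 6410 and 13900 RPKM in the other libraries. SAA3, an acute phase protein of epithelia, ranged from 745 RPKM in cyclic library 1 to 6780 RPKM in cyclic library 5, and from 716 RPKM in pregnant library 4 to 13100 RPKM in pregnant library 5.

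The first 2824 features of the deposited table are not in alphabetical order, and at least 500 features in that order follow them. The order of later features was not examined further. The sort key of the first features is not given in the sources used here. Of the 2808 tested features among the first, 81.1% had an unadjusted p under 0.05 (limma-trend), against 12.5% of the 10026 others. Across the genes of that head, which are not independent replicates, row number and p had a Spearman rho of 0.51.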
